A study of Mus musculus with 12 samples.

How the data were processed

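Gene expression was measured in microdissected olfactory epithelium of male C57BL/6J mice aged 6 weeks, on 12 one-colour Affymetrix arrays, 1 per biological replicate. Per the labels' protocols, clodronate liposomes (Lip-C), meant to deplete macrophages, were given intranasally in 50 µl and intravenously in 200 µl. Control mice received empty liposomes (Lip-O) by both routes in equal volumes. Both treatments were combined with bilateral removal of the olfactory bulbs (OBX) or a sham operation, and tissue was taken at 48 h. Groups came from the sample titles, with 3 replicates in each of 4 groups. The titles call them biological replicates. Whether RNA of several mice was pooled on an array is not given in the sources used here, so p-values describe the spread between these samples.

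The deposited values are probe set intensity on a linear scale for 45101 probe sets, 64 of them controls. The authors had scaled every array to a common level: the mean after trimming 2% was 500 on each array. Median signals ran from 117.5 to 134.2, and the array medians of log2 values differed by at most 0.17. Per the labels' protocols, biotin-labelled cRNA was made from total RNA. The algorithm that summarised probes into probe sets is not given in the sources used here. No column of values was left unused, and the largest share of identical values between any pair of arrays was 0.315%.

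Values were taken as log2(signal + 16) with no further scaling, control probe sets were left out, and a probe set was kept if it exceeded its array's 40th percentile on at least 3 arrays, which left 28986. A fold change on this scale understates the change of dim genes. Where a compared group's mean signal lay under the arrays' 40th percentile, signals are given in place of a log2 change. The platform annotation gave 1 gene to 34945 probe sets, several to 932 and none to 9160. A match by gene identifier to the reference gene table (assembly GRCm38.p6, used for names alone) was found for 34741, and no symbol changed. Each gene was represented by its probe set with the highest mean, giving 13628 genes. For no gene given in a comparison below did another probe set change in the opposite direction at an unadjusted p under 0.05. Amino acid response genes listed separately in the closing section were not part of this check. No coordinates are given because the values carry no genome build. The number of arrays limits the precision of each value: the median standard error of a log2 change between groups was 0.124.

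The means of the 4 groups were fitted in 1 model with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and 2.56 added by moderation of the variance. The 7 comparisons were each treatment within each level of the other, the interaction and both main effects, which follow the series' design of crossed factors. Tests were two-sided and adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so single genes were tested in the model alone. Errors of log2 changes are standard errors from the model, and signals are means ± SD of 3 arrays. The model was tested on simulated data with 200 changed genes among 13628 and normal noise drawn independently for each gene. Deviations shared between genes were not simulated, so recovery in the real data may differ. The model recovered 76.1% of genes changed by 1 on the log2 scale for Lip-C in sham mice. It recovered 89.6% for Lip-C in OBX mice, 82.1% for OBX in Lip-O mice, 82.1% for OBX in Lip-C mice and 49.3% for the interaction. For genes changed by 0.5, near the median size of the called changes in 3 of these comparisons, it recovered 50.7%, 35.8%, 41.8%, 46.3% and 16.4% in the same order. The adjusted threshold also depends on how many genes change. For OBX in Lip-O and Lip-C mice the simulation gave 153 and 157 calls and the real data 2676 and 2615, so recovery may be understated. For Lip-C in OBX mice and the interaction it gave 153 and 107 calls and the real data 47 and 0, so recovery may be overstated.

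Gene lists for 28 cell types and processes were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists within a comparison. Camera asks whether a list ranks above or below the other genes. The same test with an estimated correlation and fry, which asks whether the members move 1 way on balance, were run beside it. The lists covered macrophages and monocytes, class II and dendritic cells, neutrophils, lymphocytes, mast cells, mature and immature olfactory sensory neurons, neuronal precursors, the cell cycle, sustentacular cells, horizontal basal cells, Bowman glands, ciliated cells, chemokines and cytokines, acute phase, interferon response, apoptosis, growth factors, axon injury and stress, antioxidants, lysosome and uptake, ensheathing and Schwann cells, endothelium, fibroblasts and matrix, bone and cartilage, skeletal muscle, erythroid cells and odorant receptors. The mast cell list had 1 measured member and was not tested, so 27 lists entered the test.

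The lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes in each direction among genes past the threshold whose groups did not overlap, or the 5 smallest p in each direction where none passed. It added up to 4 members of each list by p, and the anchors Cd68, Adgre1, Csf1r, Omp, Gap43, Mki67, Krt5 and Cyp2g1 wherever measured; 1 further anchor is not reported here. Genes given below are a selection from those the rule named.

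Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, centring on the 75th percentile, other treatments of several probe sets per gene, the unmoderated analysis of variance that the series' design names, moderation with a trend, array weights, a fit of the compared groups alone, the replicate number as a block, and leaving out each array. Leaving out liver genes, leaving out a pair of arrays, and gene list tests without single arrays were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.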

Results

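The olfactory epithelium of mice given clodronate liposomes to deplete macrophages (Lip-C) and of control mice (Lip-O) was profiled 48 h after OBX or a sham operation, with 3 arrays in each of the 4 groups. Removing the bulb cuts the axons of olfactory sensory neurons, and the design addresses how macrophages bear on the degeneration, protection and renewal of these neurons. After log2 transformation, 13628 genes were compared. Arrays of the same group correlated at r = 0.974 to 0.985 across genes, which are not independent replicates. The principal component with the largest share of the variance (32.9%) placed all OBX arrays above 0 and all sham arrays below it. Lip-C OBX replicate 3 (2.75) and Lip-O OBX replicate 3 (10.5) lay nearest to the sham arrays.

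**Figure D1:**
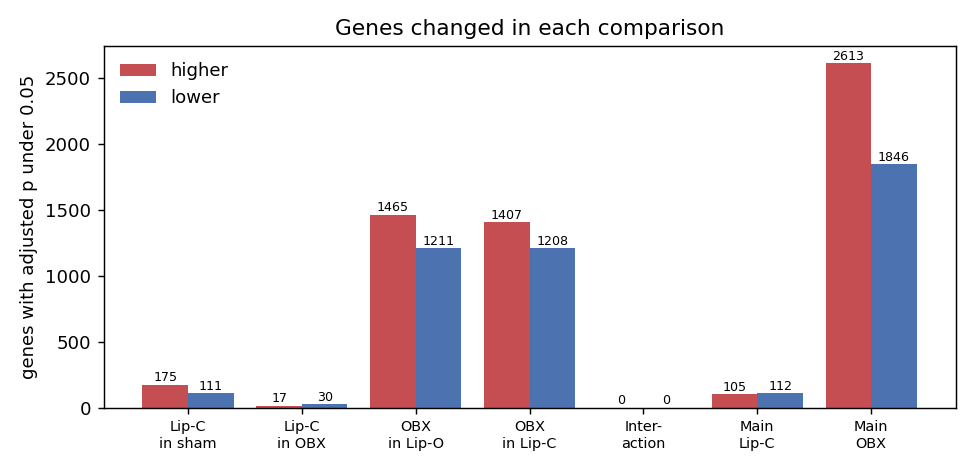
Number of genes with an adjusted p under 0.05 in each comparison (vertical axis), higher in red and lower in blue. OBX changed 2676 genes in Lip-O and 2615 in Lip-C mice, Lip-C changed 286 in sham and 47 in OBX mice, and the interaction had 0.

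In sham mice, Lip-C lowered transcription factors of olfactory neuronal precursors. Neurog1, a proneural factor of immediate neuronal precursors, fell from a signal of 251 ± 34.1 (SD, n = 3) to 90.0 ± 15.1, a log2 change of -1.34 ± 0.15 (adjusted p = 0.00612). Neurod1, which acts later in the same lineage, fell from 884 ± 43.9 to 284 ± 96.7 (-1.63 ± 0.19, adjusted p = 0.00618). Chac1, a glutathione-degrading enzyme induced by amino acid stress, rose from 239 ± 52.5 to 715 ± 63.4 (1.53 ± 0.17, adjusted p = 0.00612). Bone genes also fell: Ibsp, a bone matrix protein, changed by -1.92 ± 0.21 (adjusted p = 0.00612), and Ctsk, the collagen-cleaving protease of osteoclasts, went from 4606 ± 445 to 886 ± 156. In all, 175 genes rose and 111 fell. All 286 had groups that did not overlap, as did 29.6% of all genes, against 10% by chance.

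Of 19 measured precursor genes, 4 fell and none rose, and 6 fell when adjusted over the list alone. Beside Neurog1 and Neurod1 these were Hes6 (-0.71) and Elavl4 (-0.54), and the list ranked below other genes (adjusted p = 1.5e-05, and adjusted p = 0.425 with an estimated correlation). The neuropeptide precursor Scg2 fell by 1.43, while 23 of 24 mature neuron genes did not pass. Omp, the marker of mature neurons, differed by -0.11 ± 0.17. Among macrophage genes, 2 of 36 fell, both over all genes and adjusted over the list alone: the growth factor receptor Csf1r (-0.83 ± 0.18, adjusted p = 0.0426) and Aif1 (-0.90 ± 0.20, adjusted p = 0.047). The lysosomal marker Cd68 differed by -0.24 ± 0.26 (adjusted p = 0.619) and Adgre1, which encodes F4/80, by -0.20 ± 0.19 (adjusted p = 0.578). The macrophage list itself did not pass (adjusted p = 0.0706).

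Of 12 bone and cartilage genes, 3 fell (5 adjusted over the list alone), among them Dmp1 of osteocytes (-3.84 ± 0.68) and Acp5 of osteoclasts (-3.06 ± 0.54), and the list ranked low (adjusted p = 0.000231, and adjusted p = 0.754 with an estimated correlation). None of 17 fibroblast and matrix genes passed over all genes, whereas 11 fell and 1 rose adjusted over the list alone; Col1a2, a chain of type I collagen, differed by -1.23 ± 0.32 (list adjusted p = 4.36e-05, and adjusted p = 0.754 with an estimated correlation). No cell cycle gene of 40 passed either way, although 37 had negative changes (list adjusted p = 9.81e-07, and adjusted p = 0.811 with an estimated correlation). Mki67, a protein of dividing cells, differed by -0.15 ± 0.32. All 17 ciliated cell genes had negative changes, 3 of them past the threshold adjusted over the list alone and 0 over all genes. Their list ranked low (adjusted p = 7.13e-06, and adjusted p = 0.425 with an estimated correlation). Krt14 of basal cells fell by 0.90 and Aldh1a7 of sustentacular cells by 0.64; Krt5 differed by -0.29, Gap43 by -0.14 and Cyp2g1 by -0.16. Higher transcripts included the hormone Fgf21 (1.53), asparagine synthetase Asns (0.71), Ms4a3 of myeloid progenitors (1.70) and Myrf, which rose from a signal under the arrays' 40th percentile (20.8 ± 6.21) to 98.6 ± 7.60.

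The number of genes changed by Lip-C in sham mice fell without any 1 of the 6 sham arrays, in fits that leave 2 arrays in a group. It was 96, 24 and 19 without Lip-O sham replicates 1, 2 and 3, and 169, 40 and 17 without Lip-C sham replicates 1, 2 and 3. It was 189 and 148 without Lip-C OBX replicates 1 and 2. Neurog1, Neurod1, Scg2, Chac1 and Ibsp passed in every leave-one-out fit, and with the mean of its probe sets Neurog1 reached -0.77 (adjusted p = 0.056). Without Lip-C sham replicate 3 the adjusted p was 0.1 for Dmp1, 0.0949 for Acp5, 0.0865 for Ctsk, 0.103 for Krt14 and 0.0629 for Ms4a3. Without Lip-O sham replicate 2 it was 0.0911 for Hes6, 0.128 for Elavl4, 0.0856 for Asns, 0.136 for Csf1r and 0.13 for Aif1. Without Lip-O sham replicate 3 it was 0.0806 for Fgf21, 0.0594 for Aldh1a7 and 0.0682 for Myrf. These 13 genes lost the call without 2 to 9 of the 12 arrays; Csf1r and Aif1 lost it without 9, including all 6 sham arrays. Aif1 also missed it with quantile normalization (adjusted p = 0.0546), and Csf1r with the mean of its probe sets (adjusted p = 0.103).

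**Figure D2:**
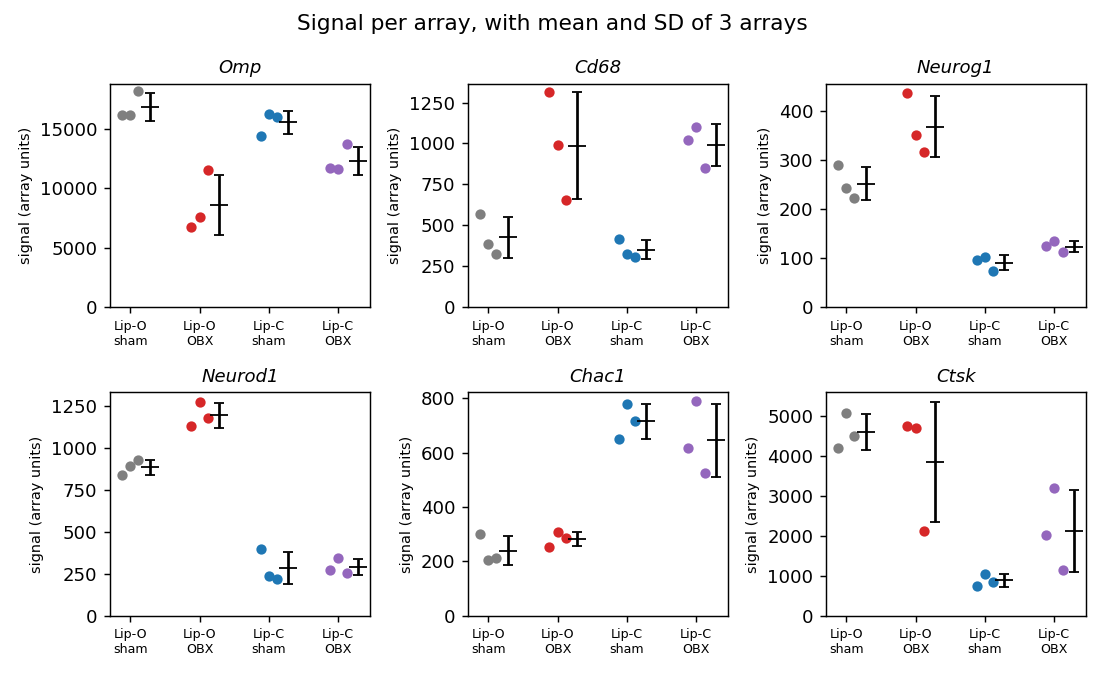
Signal of 6 genes on each array (points, linear array units), by group, with the mean and SD of 3 arrays beside them. Neurog1 and Neurod1 were lower and Chac1 higher in both Lip-C groups, Cd68 was higher in both OBX groups, and Ctsk was lowest in Lip-C sham mice (886 ± 156).

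After OBX, Lip-C again lowered genes of the neuronal precursor lineage. Neurog1 was 368 ± 62.1 in Lip-O and 123 ± 11.1 in Lip-C mice (-1.45 ± 0.15, adjusted p = 0.00396, n = 3 per group). Neurod1 fell from 1194 ± 74.8 to 290 ± 46.2 (-1.99 ± 0.19, adjusted p = 0.00362). St18, a zinc finger transcription factor, fell from 188 ± 5.30 to 34.8 ± 10.4, under the arrays' 40th percentile, and Mfng, a Notch-modifying glycosyltransferase, fell by 1.28. The bombesin-like peptide gene Grp fell by 1.35. Fgf21 rose from 56.5 ± 13.3, under that percentile, to 242 ± 46.4, and Chac1 (1.13 ± 0.17), Asns (0.74 ± 0.12) and the orphan nuclear receptor Nr4a3 (1.69 ± 0.24) rose. In all, 17 genes rose and 30 fell, each with groups that did not overlap, while 16% of all genes had such groups against 10% by chance.

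Of 19 precursor genes 4 fell, the others being Hes6 (-0.77) and Gadd45g (-0.80), and 8 fell adjusted over the list alone; the list had an adjusted p = 3.96e-09, and adjusted p = 0.183 with an estimated correlation. Macrophage genes had 0 of 36 past the threshold in limma, with 1 higher adjusted over the list alone (list adjusted p = 0.508). Cd68 differed by 0.05 ± 0.26, Adgre1 by 0.03 ± 0.19 and Csf1r by -0.28 ± 0.18. Scg2 fell by 1.31 and was the only called gene among 24 of the mature neuron list. Of that list 22 had positive changes (list adjusted p = 0.00108, and adjusted p = 0.749 with an estimated correlation), and Omp differed by 0.55 ± 0.17 (adjusted p = 0.209). The immature neuron list ranked low with 2 of 21 genes lower adjusted over the list alone and 0 over all genes (list adjusted p = 0.0097, and adjusted p = 0.749 with an estimated correlation). Its growth cone protein Gap43 differed by 0.02, and the basal cell keratin Krt5, Mki67 and Cyp2g1 differed by 0.03, 0.01 and 0.03. Sustentacular genes had 1 of 20 lower, Aldh1a7 (-0.54), and 6 adjusted over the list alone (list adjusted p = 0.00415, and adjusted p = 0.338 with an estimated correlation).

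All 28 interferon response genes had negative changes with none past the threshold either way; Mx1, an antiviral GTPase, differed by -0.74 ± 0.33 (list adjusted p = 4.43e-05, and adjusted p = 0.749 with an estimated correlation). Of the ciliated cell genes, 16 of 17 had positive changes and 5 passed adjusted over the list alone, with 0 over all genes; Tppp3 differed by 0.45 (list adjusted p = 9.3e-06, and adjusted p = 0.338 with an estimated correlation). All 12 endothelial genes had positive changes, 1 of them past the threshold adjusted over the list alone and 0 over all genes (list adjusted p = 0.000643, and adjusted p = 0.749 with an estimated correlation). The neutrophil list (0 of 18, 1 higher adjusted over the list alone, list adjusted p = 0.0311) and the fibroblast list (0 of 17 either way, list adjusted p = 0.0319) ranked high. Both had an adjusted p = 0.749 with an estimated correlation. The cartilage proteoglycan Acan differed by 2.35 ± 0.48 (adjusted p = 0.0829), and Chad, another cartilage matrix protein, rose by 1.32. Alb, which encodes albumin, was lower in Lip-C mice (adjusted p = 0.0334), where it lay under the arrays' 40th percentile, with signals of 526.6, 1184.3 and 151.3 on the Lip-O OBX arrays and at most 52.2 on any other array.

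The 47 genes changed by Lip-C in OBX mice became 7 without Lip-O OBX replicate 1, 76 without Lip-O OBX replicate 3, and 13, 19 and 19 without Lip-C OBX replicates 1, 2 and 3. Neurog1, Neurod1, St18, Mfng and Grp passed in every leave-one-out fit. Without Lip-O OBX replicate 1 the adjusted p was 0.0517 for Scg2, 0.0866 for Fgf21, 0.106 for Chac1 and for Gadd45g, 0.131 for Hes6, 0.148 for Asns, 0.0944 for Nr4a3, 0.11 for Aldh1a7, 0.132 for Chad, and 0.169 for Ms4a3 and for Alb. Except for Scg2, these calls were also lost without 2 to 8 other arrays. Without Lip-O OBX replicate 3, Omp passed (adjusted p = 0.0211). Without Lip-C OBX replicate 3, Acan passed (adjusted p = 0.0297). Alb missed the threshold with a pseudocount of 1 (adjusted p = 0.0627). The neutrophil, mature neuron, immature neuron, fibroblast and endothelial calls were lost without 4, 2, 2, 3 and 1 arrays, with highest adjusted p of 0.199, 0.117, 0.219, 0.441 and 0.0704; Lip-C OBX replicate 1 was among those arrays for all but the mature neuron list, which lost its call without Lip-O OBX replicate 1 or Lip-C OBX replicate 3.

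The Lip-C comparisons in sham and OBX mice contrast different arrays but share the estimate of each gene's spread. With that limit, they had 15 lower genes in common, where independent lists would share 0.244, and 4 higher genes, against 0.218. The lower genes included Neurog1, Neurod1, Hes6, Scg2, St18, Mfng, Grp and Aldh1a7, and the 4 higher genes were Chac1, Asns, Fgf21 and Ms4a3. Of the 175 genes raised and 111 lowered in sham mice, 87 and 69 changed in the same direction in OBX mice. Of the 17 raised and 30 lowered in OBX mice, 14 and 28 changed in the same direction in sham mice. Across all genes, which are not independent replicates, the changes correlated at r = 0.0805.

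In Lip-O mice, OBX lowered genes of mature olfactory neurons and raised genes of phagocytes. Omp fell from 16860 ± 1170 to 8610 ± 2550 (SD, n = 3), 2.01-fold lower (adjusted p = 0.00399, with a standard error of 0.17 on the log2 scale). The calcium-stimulated phosphodiesterase Pde1c (-1.43 ± 0.20), the G protein exchange factor Ric8b (-1.32 ± 0.21), the adhesion molecule Ncam2 (-1.09 ± 0.14) and the G protein subunit Gnb1 (-0.60 ± 0.09) also fell. Cd68 rose from 426 ± 126 to 986 ± 328 (1.16 ± 0.26, adjusted p = 0.0116). The complement component C1qc (1.15 ± 0.23) and Ms4a7 (0.95 ± 0.18) rose with it, as did the scavenger receptor Msr1, from 45.7 ± 15.6, under the arrays' 40th percentile, to 100.5 ± 19.7. In all, 1465 genes rose and 1211 fell. Of these, 2647 had groups that did not overlap, as did 37.7% of all genes, against 10% by chance.

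Of 24 mature neuron genes 19 fell and none rose, 20 adjusted over the list alone (list adjusted p = 9.25e-12, and adjusted p = 0.252 with an estimated correlation). Of 30 odorant receptors 16 fell, 18 adjusted over the list alone, among them Olfr17 (-1.81 ± 0.19) and Olfr15 (-1.39 ± 0.16), with a list adjusted p = 2.84e-11, and adjusted p = 0.154 with an estimated correlation. The calcium-binding protein gene Scgn fell by 2.16. Of 36 macrophage genes 7 rose and 1, Emilin2, an extracellular matrix glycoprotein, fell (-0.74); the counts were equal adjusted over the list alone (list adjusted p = 0.00448, and adjusted p = 0.796 with an estimated correlation). Csf1r differed by 0.20 ± 0.18 and Adgre1 by 0.26 ± 0.19, without passing. Of 28 lysosome and uptake genes 13 rose and none fell, 18 adjusted over the list alone, including the protease Ctsd (0.77), the cholesterol exporter Abca1 (1.21), the scavenger receptor Stab1 (0.79) and the receptor kinase Axl (0.75). That list had an adjusted p = 1.95e-06, and adjusted p = 0.295 with an estimated correlation.

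Growth factor genes had 6 of 21 higher over all genes and adjusted over the list alone, including Bmp7 (0.82), Tgfb2 (0.73) and Hbegf (0.68), with a list adjusted p = 0.00869, and adjusted p = 0.252 with an estimated correlation. Horizontal basal cell genes, of the reserve stem cells, had 3 of 11 higher, Itga6 (0.62), Lamb3 (0.56) and the stem cell factor Trp63 (0.48), and 5 adjusted over the list alone (list adjusted p = 0.00946, and adjusted p = 0.347 with an estimated correlation). Ensheathing and Schwann cell genes had 2 of 10 higher, among them Sox10 (1.15), and 4 adjusted over the list alone (list adjusted p = 0.00638, and adjusted p = 0.252 with an estimated correlation). Sustentacular genes had 6 of 20 higher, including Muc2 (0.74) and Cyp1a2 (0.55), and 7 adjusted over the list alone (list adjusted p = 0.0184, and adjusted p = 0.295 with an estimated correlation). Ciliated cell genes had 8 of 17 lower, including Spa17 (-0.68) and Tekt1 (-0.62), and 9 adjusted over the list alone (list adjusted p = 8.61e-05, and adjusted p = 0.288 with an estimated correlation). The cell cycle list ranked high with 38 of 40 changes positive, yet its only called gene, Cks2, fell by 0.45, and none passed adjusted over the list alone (list adjusted p = 0.0141, and adjusted p = 0.796 with an estimated correlation). Precursor genes went both ways, with 4 of 19 higher and 2 lower, or 7 and 3 adjusted over the list alone (list adjusted p = 0.224), and Neurog1 rose by 0.52. Bowman gland genes had 5 of 18 higher both over all genes and adjusted over the list alone (list adjusted p = 0.31), with Aqp5 at 0.90. Krt5 (0.46 ± 0.16), Mki67 (0.66 ± 0.32), Gap43 (0.28 ± 0.19) and Cyp2g1 (0.00) did not pass. The cell death genes Casp12 (0.79) and Bcl2l11 (0.64) rose and Apaf1 fell (-0.66). Liver transcripts rose too, from sham signals under the arrays' 40th percentile that allow no fold: Alb from 38.9 ± 19.2 to 621 ± 523, Ttr from 18.9 ± 12.6 to 215 ± 140 and Ahsg from 14.7 ± 3.43 to 135 ± 28.6.

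The 2676 genes changed by OBX in Lip-O mice became 1403 without Lip-O OBX replicate 1, and 1773 and 1534 without Lip-O sham replicates 2 and 3. The called genes named for this comparison kept the call in every leave-one-out fit, except Cks2 and Neurog1. Without Lip-O OBX replicate 1 the adjusted p was 0.0862 for Cks2 and 0.116 for Neurog1, and both also lost the call without Lip-O sham replicates 2 and 3 and without 1 more Lip-O OBX array (replicate 3 for Cks2, replicate 2 for Neurog1). Krt5 passed without Lip-C OBX replicate 2 or 3 (lowest adjusted p = 0.0194). With the mean of a gene's probe sets the adjusted p was 0.127 for Msr1, 0.0669 for Bmp7, 0.0613 for Sox10, 0.164 for Trp63, 0.133 for Neurog1 and 0.51 for Cks2. The macrophage list missed the threshold without Lip-O sham replicate 3 or Lip-O OBX replicate 1 (highest adjusted p = 0.0762). The cell cycle list missed it without Lip-O sham replicate 1 or Lip-O OBX replicate 2 (0.492). The sustentacular list missed it without Lip-O sham replicate 2 or Lip-O OBX replicate 3 (0.0829).

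In Lip-C mice, OBX raised macrophage genes as well. Cd68 rose from 351 ± 59.6 to 991 ± 128 (1.46 ± 0.26, adjusted p = 0.0069, n = 3 per group), Aif1 by 1.13 ± 0.20, Ms4a7 by 1.12 ± 0.18 and Csf1r by 0.75 ± 0.18. Of the mature neuron genes, Pde1c (-1.06 ± 0.20), the calcium exchanger Slc24a4 (-1.10 ± 0.15) and Gnb1 (-0.49 ± 0.09) fell, while Omp went from 15570 ± 979 to 12330 ± 1190, a change of -0.34 ± 0.17 that did not pass (adjusted p = 0.176). Bone and cartilage genes rose: Col2a1, the collagen of cartilage, went from 141 ± 20.2 to 907 ± 514, and Dmp1 from 140 ± 62.0 to 1211 ± 835. In all, 1407 genes rose and 1208 fell. Of these, 2579 had groups that did not overlap, as did 40.2% of all genes, against 10% by chance.

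Of 24 mature neuron genes 14 fell, 17 adjusted over the list alone with 2 higher (list adjusted p = 3.69e-07, and adjusted p = 0.284 with an estimated correlation). Odorant receptors had 12 of 30 lower, 13 adjusted over the list alone, such as Olfr976 (-1.43) and Olfr17 (-1.06), with a list adjusted p = 1.14e-06, and adjusted p = 0.284 with an estimated correlation. Of 36 macrophage genes 15 rose, and 16 rose with 1 lower adjusted over the list alone (list adjusted p = 3.72e-05, and adjusted p = 0.545 with an estimated correlation). Of 28 lysosome and uptake genes 16 rose, 17 adjusted over the list alone, including Stab1 (0.86), Hexa (0.70) and Ctsz (0.69), with a list adjusted p = 3.31e-06, and adjusted p = 0.284 with an estimated correlation. Of 40 cell cycle genes 10 rose, among them Ube2c (1.06), Ccnb2 (0.94) and Aurka (0.59), and 28 rose adjusted over the list alone (list adjusted p = 3.69e-07, and adjusted p = 0.518 with an estimated correlation). Mki67 differed by 0.82 ± 0.32 (adjusted p = 0.0953). Horizontal basal cell genes had 5 of 11 higher, and 5 adjusted over the list alone, including Krt14 (0.96), Krt5 (0.79) and Lamb3 (0.72), with a list adjusted p = 0.000985, and adjusted p = 0.284 with an estimated correlation.

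Bone and cartilage genes had 8 of 12 higher and 12 adjusted over the list alone, with Dmp1 at 2.84 ± 0.68, Acan at 2.04 ± 0.48 and Matn1 going from 53.1 ± 22.8, under the arrays' 40th percentile, to 393 ± 236 (list adjusted p = 5.41e-05, and adjusted p = 0.324 with an estimated correlation). Fibroblast and matrix genes had 10 of 17 higher and 14 adjusted over the list alone, including Tnc (1.32) and Fn1 (0.82), with a list adjusted p = 7.56e-06, and adjusted p = 0.313 with an estimated correlation. Bowman gland genes had 3 of 18 higher, both over all genes and adjusted over the list alone, among them the water channel Aqp5 (0.64) and the gland factor Sox9 (0.76), with a list adjusted p = 0.000985, and adjusted p = 0.284 with an estimated correlation. Ciliated cell genes had 4 of 17 higher, among them Dnah5 (0.94) and Ak7 (0.74), and 6 adjusted over the list alone, with a list that did not pass (adjusted p = 0.0508). Endothelial genes had 2 of 12 higher, including Cldn5 (0.52), and 4 adjusted over the list alone (list adjusted p = 0.00746, and adjusted p = 0.518 with an estimated correlation). The growth factor list (3 of 21 higher, 3 adjusted over the list alone), the ensheathing list (2 of 10, 5 adjusted over the list alone) and the sustentacular list (3 of 20, 3 adjusted over the list alone) each had an adjusted p = 0.0169, and adjusted p = 0.284 with an estimated correlation. Casp12 rose by 0.58 and Apaf1 fell by 0.57, while Adgre1, Gap43 and Cyp2g1 differed by 0.49, 0.44 and 0.20 without passing.

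The 2615 genes changed by OBX in Lip-C mice became 838 and 1042 without Lip-C OBX replicates 1 and 2, and 1052 and 1215 without Lip-C sham replicates 2 and 3. Without Lip-C OBX replicate 1 the adjusted p was 0.0737 for Acan, 0.098 for Matn1, 0.106 for Col2a1, 0.0843 for Tnc, 0.0965 for Fn1, 0.0598 for Sox9, 0.104 for Dnah5 and 0.0687 for Ak7. Without Lip-C OBX replicate 2 it was 0.075 for Dmp1, 0.0775 for Ube2c, 0.0828 for Ccnb2 and 0.07 for Csf1r, and without Lip-C sham replicate 2 it was 0.0949 for Aurka. These 13 calls were lost without 2 to 5 of the 12 arrays, all of them Lip-C arrays. Csf1r also missed the threshold with the mean of its probe sets (adjusted p = 0.0732). Omp passed without Lip-O OBX replicate 3 (adjusted p = 0.038). The growth factor list missed the threshold without Lip-C sham replicate 2 (adjusted p = 0.0607), the endothelial list without Lip-C OBX replicate 1 (0.0505), and the sustentacular list with quantile normalization (0.106).

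**Figure D3:**
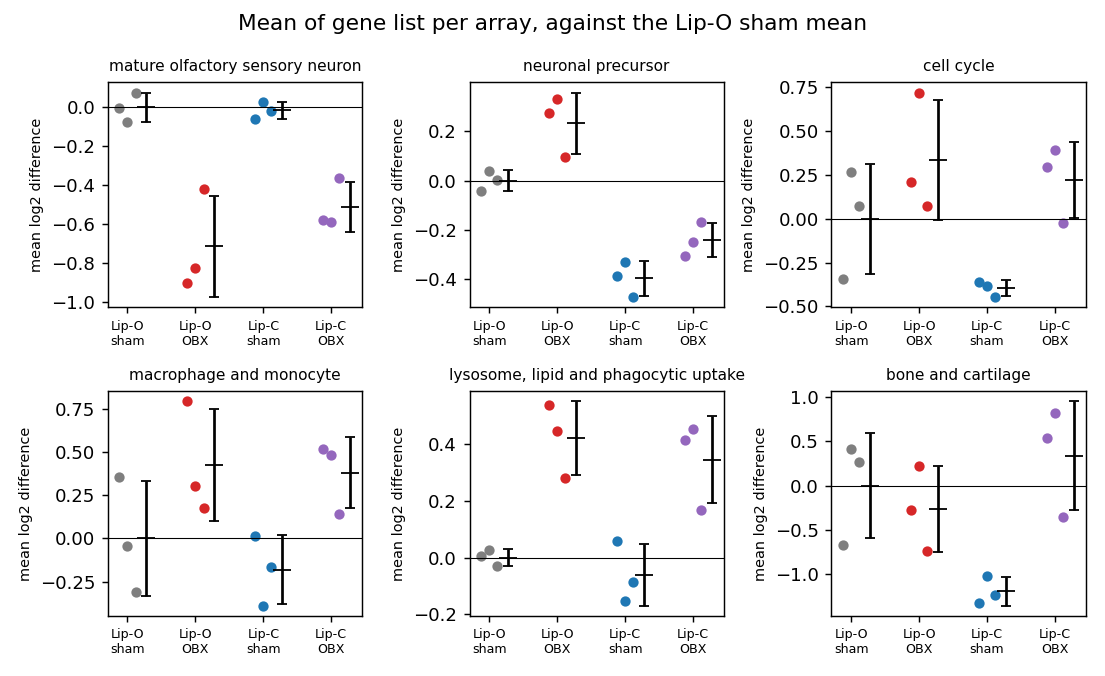
Mean log2 difference of 6 gene lists on each array from the Lip-O sham mean (vertical axis), by group, with the mean and SD of 3 arrays beside the points. Precursor genes were lower on all 6 Lip-C arrays than on the 6 Lip-O arrays, and mature neuron genes were lower on all 6 OBX arrays than on the 6 sham arrays.

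Whether Lip-C altered the response to OBX was tested as an interaction. No gene passed in limma (0 of 13628), while 2405 genes had an unadjusted p under 0.05 against 681.4 by chance, and 223 had an adjusted p under 0.10. The unmoderated analysis of variance gave 2389 genes at unadjusted p, and a fit without Lip-O OBX replicate 2 gave 155 past the threshold, without Lip-C OBX replicate 3 it gave 3. The smallest adjusted p was 0.0747, shared by the stress-hormone-responsive Fkbp5 (-1.58 ± 0.23), Pcif1 (-0.81 ± 0.12), Agap1 (-0.70 ± 0.10), Nr4a1 (1.05 ± 0.14), Spata33 (0.93 ± 0.14), and the hyaluronan synthase Has2 and the histone gene H3c11, whose signals lay under the arrays' 40th percentile in at least 1 group. The change in Omp with OBX differed between Lip-C and Lip-O mice by 0.67 ± 0.24 (adjusted p = 0.191), and that in Cd68 by 0.30 ± 0.36 (adjusted p = 0.71). Macrophage genes had 0 of 36 past the threshold either way (list adjusted p = 0.409). The OBX comparisons in Lip-O and Lip-C mice contrast different arrays but share the estimate of each gene's spread. With that limit, 431 genes rose in both, where independent lists would share 151, and 597 fell in both, against 107. Changes in the OBX comparisons correlated at r = 0.451 across genes, which are not independent replicates.

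As a main effect over both surgeries, Lip-C raised 105 genes and lowered 112. Of 19 precursor genes 6 fell, 10 adjusted over the list alone (list adjusted p = 1.83e-10, and adjusted p = 0.126 with an estimated correlation). Of 36 macrophage genes 0 passed in limma, against 1 higher and 4 lower adjusted over the list alone; Csf1r differed by -0.56 ± 0.12 (adjusted p = 0.0593) and Cd68 by -0.10 ± 0.18. The interferon list ranked low (adjusted p = 6.07e-05, and adjusted p = 0.801 with an estimated correlation), as did the acute phase list (adjusted p = 0.0232) and the chemokine and cytokine list (adjusted p = 0.0485), both with adjusted p = 0.801 with an estimated correlation. Lip-O sham replicate 1 stood apart in these lists, with means of 0.76 for interferon, 1.49 for acute phase and 1.47 for chemokine genes on the log2 scale relative to its group's mean. The other Lip-O sham arrays had -0.31 and -0.45, -0.59 and -0.90, and -0.73 and -0.74. Without it the interferon list still passed (adjusted p = 0.0194). Acute phase genes lost the call without 3 arrays and chemokine genes without 6, Lip-O sham replicate 1 and Lip-O OBX replicate 1 among them in both cases, with highest adjusted p of 0.533 and 0.826. With the mean of a gene's probe sets both lists missed the threshold (adjusted p = 0.0707 for acute phase and 0.0613 for chemokine genes). Quantile normalization also ended the chemokine call (0.0649). The 217 genes became 126, 95 and 99 without Lip-O sham replicates 1, 2 and 3, 106 and 107 without Lip-O OBX replicates 1 and 2, 91 and 84 without Lip-C sham replicates 2 and 3, and 90 and 109 without Lip-C OBX replicates 1 and 2.

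As a main effect over both liposome groups, OBX raised 2613 genes and lowered 1846. Cd68 rose by 1.31 ± 0.18 (adjusted p = 0.000715), Csf1r by 0.48 ± 0.12, Krt5 by 0.63 ± 0.11 and Mki67 by 0.74 ± 0.23, and Omp fell by 0.67 ± 0.12. Lists that did not pass for OBX included class II and dendritic cells (adjusted p = 0.358), lymphocytes (0.627), apoptosis (0.542), axon injury and stress (0.172), antioxidants (0.198), skeletal muscle (0.942) and erythroid cells (0.213). The measured mast cell gene, Cma1, had signals near or under the arrays' 40th percentile: 70.8 ± 4.58 in Lip-O sham, 62.4 ± 4.80 in Lip-O OBX, 49.4 ± 11.5 in Lip-C sham and 64.9 ± 26.0 in Lip-C OBX mice.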

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

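The tests on separate lists of osteoclast, bone-forming cell and cartilage genes were chosen only after the change of bone genes had been seen. The 5 gene groups below differed in their response to OBX between Lip-C and Lip-O mice by camera's test of the interaction, although no single gene passed in limma. Ciliated cell genes had a median interaction of 0.598 on the log2 scale, positive for 17 of 17 genes, 13 of which passed adjusted over the list alone. With OBX, 8 of 17 fell in Lip-O mice, as Tekt1 did (-0.62), and 4 of 17 rose in Lip-C mice. Relative to Lip-O sham mice the list's mean was -0.338 in Lip-O OBX, -0.305 in Lip-C sham and -0.0619 in Lip-C OBX mice, so the low Lip-C sham level contributes. Their list had an adjusted p = 8.83e-10 in the interaction, and adjusted p = 0.237 with an estimated correlation. Fry gave an adjusted p = 0.00969 for ciliated genes, and did not pass for mature neuron and cell cycle genes (0.823 each) or for fibroblast and bone genes (0.198 each). Tekt1 itself differed by 0.66 ± 0.14 (adjusted p = 0.0866). Mature neuron genes had a median of 0.157 (20 of 24 positive, adjusted p = 0.0455) and cell cycle genes of 0.307 (36 of 40 positive, adjusted p = 0.00929), both with adjusted p = 0.948 with an estimated correlation and with no gene past the threshold adjusted over the list alone. The mature neuron result was lost without any 1 of 7 arrays: Lip-O sham 1 and 3, Lip-O OBX 1 and 2, Lip-C sham 1 and 3 and Lip-C OBX 3 (highest adjusted p = 0.304), and with quantile normalization (0.0892). The cell cycle result was lost without Lip-O sham 2, Lip-O OBX 1, Lip-O OBX 3 or Lip-C OBX 2 (highest adjusted p = 0.202).

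Bone and cartilage genes had a median interaction of 1.76, positive for 11 of 12 genes, all 11 of which passed adjusted over the list alone. The adjusted p was 4.77e-06, and 0.842 with an estimated correlation. Dmp1 differed by 3.32 ± 0.97 (adjusted p = 0.135), Acan by 2.18 ± 0.67 (adjusted p = 0.15) and Ibsp by 1.24 ± 0.30 (adjusted p = 0.105). The 13 cartilage genes of a separate list were higher with Lip-C in OBX mice by 1.35 (95% interval 0.495 to 2.2), with 1.57 and 1.38 on Lip-C OBX 1 and 2 against 0.25 on Lip-C OBX 3, relative to the mean of all arrays. Fibroblast and matrix genes had a median of 0.797, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 4.8e-06, and adjusted p = 0.842 with an estimated correlation). Col1a2 differed by 1.48 ± 0.46 (adjusted p = 0.149). The ciliated, bone and fibroblast results passed in each of the 12 leave-one-out fits.

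The fall of bone genes in Lip-C sham mice argues against a loss of osteoclasts alone, since a list of 9 genes of bone-forming cells also changed, by a mean of -1.61 (upper end of the 95% interval -0.682). That list holds Dmp1 and Ibsp, already seen to fall. Its 7 other genes changed by -1.25 (95% interval -2.18 to -0.325). Only named genes past the threshold were left out, so these 7 may include others already seen to fall. The 11 osteoclast genes, with none left out, changed by -0.855 (-1.33 to -0.382). The 13 cartilage genes changed by -0.256 (-1.11 to 0.598), which leaves open whether cartilage fell. Less bone in the dissected Lip-C sham samples may therefore account for the pattern, which is a hypothesis found and tested on the same arrays. In sham mice the osteoclast list fell less than the bone-forming cell list, which holds Dmp1 and Ibsp, by 0.758 (95% interval 0.15 to 1.37). In OBX mice the difference was -0.37 (-0.979 to 0.238). Over both surgeries the difference per array was 0.194 (exact permutation p = 0.445 over 400 stratified splits), which cannot be told apart from equal changes. Other cells' expression of listed genes could dilute a list's mean and was not measured. Whether osteoclasts were lost beyond bone-forming cells therefore stays open. Depletion of osteoclasts, relatives of macrophages, along with other bone cells stays open as a biological explanation and was not tested further.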

How the results depend on the processing

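The fits without liver genes, without Lip-O OBX 3 and Lip-C OBX 3 together, and of gene lists without single arrays were chosen only after the results had been seen. Apart from leave-one-out, 859 values of named genes kept their direction and side of the threshold, 21 lost it, 2 gained it and 3 reversed; in leave-one-out fits these were 1799, 294, 12 and 19. Gene list calls kept it in 348 cases and lost it in 100, and in 712 and 56 in leave-one-out fits, none reversing. The reversals were of genes near 0 that did not pass: Mki67 with Lip-C in OBX mice (-0.0113, 75th percentile centring) and Cyp2g1 with OBX in Lip-O mice (-0.0204, quantile normalization; -0.0054, 75th percentile centring).

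Counts for Lip-C in sham mice, Lip-C in OBX mice, OBX in Lip-O mice, OBX in Lip-C mice, the interaction and the main effect of Lip-C are named below where they moved by over 1.5 times; the main effect of OBX did not at any setting run. With no filter Lip-C in sham mice gave 56, OBX in Lip-C mice 1736, the interaction 1 and the main effect of Lip-C 106. With a filter at the 60th percentile, which tests fewer genes, Lip-C gave 548 in sham and 72 in OBX mice and the interaction 85. The analysis of variance gave 7 for Lip-C in OBX mice and 126 for its main effect; at unadjusted p it gave 2883, 1686, 4542, 4667, 2389 and 2269 in the order above. Moderation with a trend gave 615 and 97 for Lip-C in sham and OBX mice, 107 for the interaction and 326 for the main effect of Lip-C. Array weights gave 1262 for Lip-C in sham mice, 4058 for OBX in Lip-C mice, 30 for the interaction and 351 for the main effect of Lip-C. Every probe set on its own gave 838 for Lip-C in sham mice and 3 for the interaction. The compared groups alone, with fewer samples for the spread, gave 79 and 2 for Lip-C in sham and OBX mice and 1574 for OBX in Lip-O mice. Without Lip-O OBX 3 and Lip-C OBX 3 together the interaction had 1. Except where fewer genes or samples were used, the cause was not tested. Camera gave 64 list calls, an estimated correlation 0 and fry 40, of which 38 were among the 64, most of them for OBX. For Lip-C, fry shared the precursor call in sham mice, OBX mice and the main effect (adjusted p = 0.019, 0.00484 and 0.000812). It also shared the ciliated call in sham mice (0.0303), the sustentacular main effect (0.0166) and, in the interaction, only the ciliated call. Other Lip-C calls did not pass with fry, including cell cycle (0.354), fibroblast (0.187) and bone genes (0.148) in sham mice. Interferon and mature neuron genes in OBX mice had 0.557.

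Leaving out single arrays gave 17 to 314 genes for Lip-C in sham mice, 7 to 76 for Lip-C in OBX mice, 1403 to 2793 for OBX in Lip-O mice, 838 to 3030 for OBX in Lip-C mice, 0 to 155 for the interaction, 84 to 258 for the main effect of Lip-C and 3466 to 4679 for that of OBX. Fits that left out an array kept 2 or 3 in each group. Genes that changed sign ranged from -0.476 to 0.169 (Mki67, Lip-C in sham mice), and with Lip-C in OBX mice from -0.207 to 0.285 (Cd68), -0.166 to 0.198 (Adgre1), -0.198 to 0.165 (Gap43), -0.19 to 0.251 (Mki67), -0.113 to 0.227 (Krt5) and -0.0045 to 0.092 (Cyp2g1); Cyp2g1 with OBX in Lip-O mice ranged from -0.0545 to 0.0504.

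With the replicate number as a replicate block the counts were 329, 45, 2971, 2997, 0, 243 and 4774, in the order above with the main effect of OBX last. After removal of group means, 10 of 18 pairs of arrays with the same number had r over 0.1 (median 0.128, against -0.0892 for other numbers), and 9 of 12 arrays correlated best with their own number, a hint from the data and not the design that arrays share more than a number. Signal over background limits dim genes, whose changes the added 16 shrinks.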

Other observations

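The tests on neuronal precursor genes, the test of equal induction of liver genes, and the use of an interval for their array order were chosen only after the results had been seen. The other tests of liver genes, that of amino acid genes and the splits were written before. Chac1, Asns and Fgf21, higher with Lip-C in sham and in OBX mice, are targets of the response to amino acid shortage. Of 20 other genes of that response, listed before their values were seen, 19 were higher with Lip-C over both surgeries, with a mean of 0.253 on the log2 scale. The exact permutation p was 0.005, the smallest that 400 stratified splits give. Past the threshold were the serine pathway enzymes Psat1 (0.65, adjusted p = 0.0176) and Shmt2 (0.52, adjusted p = 0.00955), the stress factor Nupr1 (0.86, adjusted p = 0.0156), Pck2 (0.43, adjusted p = 0.0204) and Eprs, which charges tRNA (0.30, adjusted p = 0.0369). Ddit4 differed by -0.29 (adjusted p = 0.313). The 20 genes were tested over both surgeries together and not within each. Trib3, of the stress list, differed by 0.62 ± 0.16 with Lip-C in sham mice (adjusted p = 0.0673). In OBX mice its signal was 906 ± 107 with Lip-O and 825 ± 127 with Lip-C (interaction -0.76 ± 0.23, adjusted p = 0.142). A wider amino acid response in Lip-C mice is consistent with these values.

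Ms4a3, a gene of myeloid progenitors, was higher with Lip-C, while granule genes went both ways. Ms4a3 rose by 1.70 ± 0.23 in sham and 1.42 ± 0.23 in OBX mice, and in sham mice the granule proteases Prtn3 (1.72 ± 0.35, adjusted p = 0.0393) and Ctsg (2.31 ± 0.51, adjusted p = 0.049) rose, whereas Mmp9, a granule protease that osteoclasts also make, fell by 1.61 (adjusted p = 0.0336). Mmp9 lost its call without any 1 of the 6 sham arrays (highest adjusted p = 0.0998, without Lip-O sham replicate 2). Mpo, a granule peroxidase, differed by 2.23 ± 0.57 in sham (adjusted p = 0.0656) and 2.55 ± 0.57 in OBX mice (adjusted p = 0.109), without passing; it passed in OBX mice without Lip-O sham replicate 1 (adjusted p = 0.0313). Ctsg lost its call without any 1 of the 12 arrays and Prtn3 without 8 of them, with highest adjusted p of 0.149 and 0.125, both without Lip-C sham replicate 3. Over both surgeries the neutrophil list had 1 of 18 genes higher and 1 lower, or 8 and 1 adjusted over the list alone (list adjusted p = 0.0247, and adjusted p = 0.801 with an estimated correlation). It lost the call without 5 arrays: Lip-O sham 3, Lip-O OBX 2, Lip-O OBX 3, Lip-C sham 1 and Lip-C OBX 1 (highest adjusted p = 0.0827).

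The fall of precursor genes with Lip-C, a mean of -0.434 over both surgeries (95% interval -0.543 to -0.325), argues against a smaller share of olfactory epithelium in the samples as the whole cause: mature neuron genes changed by 0.0945, with a lower end of the interval of -0.106. Sustentacular genes, which such a smaller share would also lower, did change by -0.137 (-0.234 to -0.0389), less than the precursor genes. Scaling of the arrays is also argued against, since 8 of 8 precursor calls, those in sham and in OBX mice counted separately, stayed under both other scalings. The medians of the deposited arrays already lay within 0.17 of each other on the log2 scale, so this was a mild test. Fewer dividing cells stay open, because the cell cycle list changed by -0.116 with Lip-C in OBX mice with an interval from -0.599 to 0.367, which includes the precursor list's -0.473. In sham mice both lists changed by -0.396, the cell cycle list with an interval from -0.879 to 0.0874. A loss of macrophage signals to precursors may also account for the fall and was not tested, and neither was a direct effect of clodronate on these cells.

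Alb, Ttr and other liver transcripts were highest on the Lip-O OBX arrays, and liver RNA in these samples was weighed against induction by OBX. The test written before asked whether other liver genes follow the array order of Alb: of 6 bright genes among 32 listed, 2 (Fga and Fgg) did and Kng1, Apoc1, Uox and Ttpa did not (1 in 6 by chance, exact binomial p = 0.263). This met the outcome set beforehand to count against liver RNA, but only at its limit of 1 in 3; after the result was seen, the exact 95% interval of the share was added (4.33% to 77.7%), and it is too wide to decide, so liver RNA cannot be told apart from other sources. Of 7 other liver genes seen before the test, 5 had that order and Ahsg and Itih4 did not. All these genes were read on the same 3 arrays, so they are not the independent trials that the binomial p and interval assume. On the Lip-O sham arrays Fga and Fgg had signals of at most 17.9. Apoc1, Uox and Ttpa had at least 186.7 there and Kng1 56.9 to 726, which can mask an added signal in their order. An equal induction by OBX is argued against by all 26 listed genes on the array, whose response was lower in Lip-C than in Lip-O mice by -0.664, with a 95% interval that ends just under 0 (-1.31 to -0.0171) and with 12 of them dim in every group; a smaller induction in Lip-C mice stays open, at 0.309 (-0.271 to 0.889) for the 6 bright genes.

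Other splits of the samples were counted against each number of changed genes. Each pairwise comparison has 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes in each: 286 against at most 0 for Lip-C in sham mice, 47 against 1 for Lip-C in OBX mice, 2676 against 0 for OBX in Lip-O and 2615 against 0 for OBX in Lip-C mice. For the main effect of OBX, 1 of 100 splits, the real one, gave as many (4459, highest other 3), a share under 0.05. Other splits mix OBX and sham arrays in a group, so an OBX effect widens their spread and lowers their counts. For the main effect of Lip-C it was 2 of 100, a share under 0.05, but 1 other split gave more genes, 267 against 217. For the interaction, where no gene passed, 1 of 100 gave as many genes at unadjusted p, 2405, and the highest other gave 2292. Swapping Lip-C and Lip-O in 1 surgery alone turns the interaction into the main effect of Lip-C, which has that same number at unadjusted p. That highest count thus matches the real Lip-C effect under other labels and is no measure of a random split.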
